A study of Mus musculus with 6 samples.

How the data were processed

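Gene expression was measured in 3 colon samples of control mice and 3 of mice lacking Hdac2, which encodes the histone deacetylase HDAC2, in the intestine. The gene had been floxed and deleted with a Cre recombinase under the villin promoter, which is active in intestinal epithelial cells. Per the labels, the animals were of a background mixed from 3 strains. The source label of each sample names epithelium and 1 numbered mouse, whereas the extraction protocol in the labels speaks of RNA from the colon. The titles and genotype labels of the second group name HDAC2 alone, while its description label names both HDAC1 and HDAC2. The group is called HDAC2 KO here, after the title and genotype.

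Each sample was hybridised as biotin-labelled cRNA to 1 one-colour Affymetrix mouse array. The deposited values were made with RMA by the authors, per the submitters' processing notes, which give no version. RMA corrects the background, quantile-normalizes the probes and summarises them per probe set. The deposited values lay between 2.39 and 14.6, with array medians between 6.17 and 6.21, and were therefore taken as log2. Quantile normalization makes the arrays share 1 distribution, so a change in total RNA cannot be seen, and background correction compresses differences at low signal. Scanner files, detection calls and scan dates were not used here, so no hybridisation batch was tested. The number of arrays, 3 per group, limits the precision.

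The table held 45101 probe sets, of which 64 were array controls. Gene names came from a platform annotation of 2016: 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none listed. Of the probe sets with 1 symbol, 34741 were matched through the Entrez identifier to the RefSeq annotation of assembly GRCm38.p6, and 0 symbols changed. That annotation was used only for names and for the order of genes, since no genome build belongs to the array values. For each of 18193 genes, the probe set with the highest mean over the 6 arrays stood for the gene. The 10916 genes whose mean was at or above the 40th percentile of all genes, a log2 signal of 6.66, were tested.

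Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, group as the sole term), with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Every adjusted p given for a gene is from limma, with n = 3 arrays per group. Each difference is HDAC2 KO minus control on the log2 scale with its standard error (SE). Exact 2-sided permutation tests were used for single values. With 3 against 3 samples they cannot give a p under 0.10. The fit was tested on simulated data made for the comparison of HDAC2 KO with control, with the means and spreads of the 10916 genes and 200 changed genes. It recovered 32% of genes changed by 0.2 on the log2 scale, 60% of those changed by 0.3, 90% of those changed by 0.5 and 98% of those changed by 1. False calls made up 4.11% of all calls. The simulated noise was independent between genes and between arrays, and only 200 genes were changed, so these rates may not hold for the real data.

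In all, 49 gene lists were set up: 48 lists of cell type markers, pathways and complexes, and the 100 annotated genes on each side of Hdac2. The 47 lists with at least 3 genes tested entered limma's camera with its preset inter-gene correlation of 0.01, and passed at a Benjamini-Hochberg adjusted p under 0.05. Counts of members are given over all genes tested and adjusted over the list alone. Groups, lists, tests and the rule for named genes were fixed before the data were examined. Named are the class I histone deacetylases, the 12 called genes with the largest difference in each direction whose groups did not overlap, leaving out names that are only clone, accession or predicted-gene identifiers, and up to 4 members of each list with the smallest p. These were 195 genes. In 3 of them, H2-D1, H2-K1 and H2-DMb2, probe sets of the gene were called in opposite directions.

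Further fits fixed in advance used no signal filter, a filter at the 60th percentile, the mean of a gene's probe sets, a further quantile normalization, centring of each array on its median, an intensity trend with robust variances, array weights, the replicate number as a block, leaving out each array in turn, testing all probe sets one by one, other thresholds, and camera with an estimated correlation, on ranks, or replaced by fry. Leaving out probe sets that can bind several transcripts was added after seeing the data.

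The labels number the mice 1 to 3 in both groups. Deviations from the group means over the genes tested correlated between same-numbered arrays with r between 0.20 and 0.34, against r between -0.37 and 0.18 for other arrays of different groups, and each array correlated best with its own number. This pairing comes from the correlations and not from a label. It entered only the alternative fit with the replicate number as a block, and all other values come from the fit with group as the sole term. With the replicate number as a block, 1943 genes were called against 1952 without it.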

Results

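The data comprised 6 arrays of mouse colon samples, 3 of control and 3 of HDAC2 KO, each measuring 45101 probe sets as RMA log2 signal. The labels name 1 mouse per array, but the signals of sex-linked genes given below leave pools of several mice open. With pools, the p-values and SDs below would measure spread between pools or technical spread, not spread between mice. The labels name both epithelium and RNA of the colon, and whether whole colon was used is not given in the sources used here. Over the 10916 genes tested, arrays of the same group correlated across genes with r between 0.9964 and 0.9989, and arrays of different groups with r between 0.9907 and 0.9923. Genes are not independent replicates, so these values describe the arrays. The median SD within a group was 0.043 in control and 0.051 in HDAC2 KO. Of the 6 arrays, HDAC2 KO replicate 2 lay farthest from its group mean, with a root mean square deviation of 0.080. The difference between 3 prime and 5 prime control probe sets, a sign of RNA degradation, was 0.504 ± 0.0092 (SD, n = 3) for Actb in control and 0.484 ± 0.020 in HDAC2 KO (exact permutation p = 0.2). For Gapdh it was 0.059 ± 0.022 and 0.066 ± 0.011 (exact permutation p = 0.7).

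The design asked how the colon transcriptome differs when Hdac2 is deleted in the intestinal epithelium. The targeted gene was lower in HDAC2 KO. The Hdac2 probe set of highest signal read 10.40, 10.37 and 10.43 on the control arrays and 10.21, 10.12 and 10.24 on the HDAC2 KO arrays, a difference of -0.21 (SE 0.040, adjusted p = 0.00893), or 13.7% less signal. A second probe set was lower by 14.0%, from 9.18 ± 0.036 to 8.97 ± 0.17 (SD, n = 3, exact permutation p = 0.1). The third, near the low end of the signal at 5.10 ± 0.20 in control and 5.03 ± 0.28 in HDAC2 KO, did not separate the groups (exact permutation p = 0.7). Where these probe sets lie relative to the deleted exons was not analysed here, and a probe outside the deleted part checks nothing about the deletion. The share of epithelial RNA, on which the size of the fall depends, was not measured. The call was lost when all probe sets were tested one by one (adjusted p = 0.0768) and when probe sets able to bind several transcripts were left out (adjusted p = 0.0884), within a range of 0.00133 to 0.0884 over the alternatives.

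Hdac1, the closest paralog, was 1.11-fold higher, at 10.31 ± 0.032 in control and 10.47 ± 0.053 in HDAC2 KO (SD, n = 3, limma adjusted p = 0.0321). This call was lost without any single array other than HDAC2 KO replicate 2, the adjusted p then lying between 0.0673 and 0.109, and also without the signal filter, after centring each array on its median and in the test of all probe sets. Hdac3 differed by 0.10 (SE 0.038, adjusted p = 0.119) and was not called. Hdac8 lay below the signal filter, at 6.44 in control and 6.45 in HDAC2 KO. Of 30 tested subunits of HDAC1/2 complexes 1 was called, as was 1 of 14 other histone deacetylases and sirtuins, and adjusted over the list alone the counts were 0 and 1. Neither these lists nor that of the class I histone deacetylases passed camera (adjusted p = 0.755 for each).

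**Figure D1:**
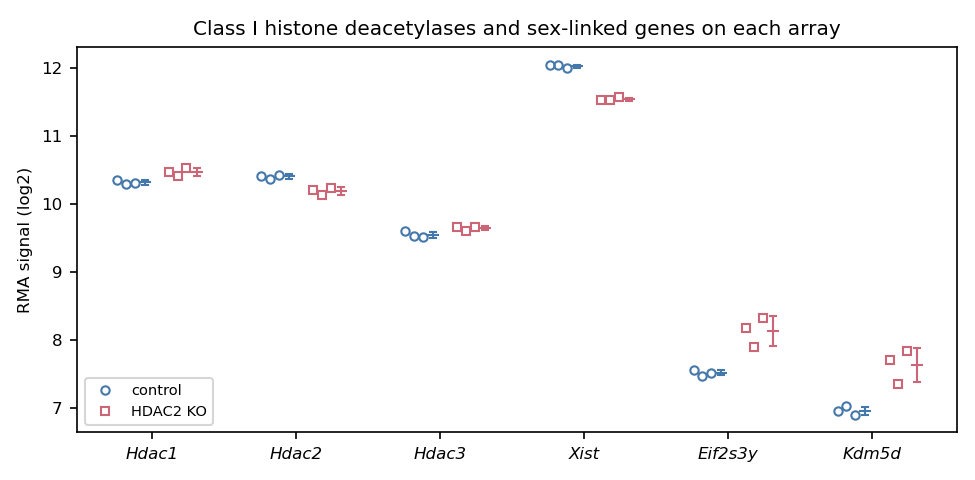
RMA signal in log2 units (vertical axis) of 3 class I histone deacetylases and 3 sex-linked genes, with control arrays as circles, HDAC2 KO arrays as squares, and bars giving mean and SD of 3 arrays. The probe set standing for Hdac2 lay lower on all 3 HDAC2 KO arrays, and those for Xist, Eif2s3y and Kdm5d lay above the filter level of 6.66 on all 6 arrays.

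Across the transcriptome, 1952 genes (17.9% of those tested) were called, 1057 higher and 895 lower in HDAC2 KO. Most differences were small: the median fold among called genes was 1.17, and 1431 differed by less than 1.25-fold. A fold of at least 1.5 was reached by 162 called genes, 60 higher and 102 lower, and a fold of at least 2 by 19 higher and 26 lower genes. The same 162 genes made up the looser list of genes with an unadjusted p under 0.05 and a fold of at least 1.5. The groups did not overlap for 4113 genes, or 37.7%, where chance gives 10%. The number of calls moved with single arrays and with weighting: 1130 genes were called without control replicate 1, 1276 without control replicate 2, 1274 without HDAC2 KO replicate 1 and 3506 with array weights. The list of at least 1.5-fold held 85 genes with the filter at the 60th percentile.

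The largest rises included secreted lectin, apolipoprotein and cytochrome P450 genes. Reg3b, a secreted C-type lectin of mucosal defence, was 11.6-fold higher, from 7.26 ± 0.063 to 10.81 ± 0.073 (SD, n = 3, limma adjusted p = 5.87e-09). Reg3g, a bactericidal lectin of the same family, was 6.24-fold higher (difference 2.64, SE 0.062), and Itln1, an intelectin that binds microbial glycans, was 2.91-fold higher (1.54, SE 0.094). The apolipoprotein genes Apoa4 and Apoa1 rose 4.50-fold and 3.51-fold. Among cytochrome P450 genes, Cyp4f14 rose 6.74-fold and Cyp2c65 rose 2.82-fold. The imprinted long non-coding RNA Meg3 was 2.98-fold higher. Sptssb, a small subunit of serine palmitoyltransferase, rose 2.74-fold, the peptide transporter gene Slc15a2 2.66-fold, the glycerophosphodiester phosphodiesterase family gene Gdpd3 2.57-fold and the membrane protein gene Mal 2.46-fold. Control signals of Cyp4f14 (6.47), Reg3g (6.11) and Slc15a2 (6.01) lay below the filter level, where RMA understates folds.

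Falls were led by genes typical of fat, T cells and mast cells. Adipoq, the adipocyte hormone adiponectin, fell by 3.02 on the log2 scale, 8.13-fold, from 10.32 ± 0.062 to 7.29 ± 0.029 (SD, n = 3, limma adjusted p = 5.87e-09). Car3, a carbonic anhydrase abundant in fat and muscle, was 6.83-fold lower, Cyp2e1 6.41-fold lower, the fatty acid binding protein gene Fabp4 4.35-fold lower and the adipokine gene Retn 2.99-fold lower. Ms4a4b, expressed in T cells, was 6.33-fold lower, and the T cell receptor segments Trbv1 and Trav9d-3 were 4.36-fold and 3.58-fold lower. The mucosal mast cell proteases Mcpt1 and Mcpt2 were 3.83-fold and 3.25-fold lower. The inducible Hsp70 genes Hspa1a and Hspa1b fell 3.37-fold and 2.90-fold. HDAC2 KO signals of Ms4a4b (5.88) and Trbv1 (6.19) lay below the filter level, which limits their folds in the same way. The limma adjusted p of these 24 genes, whose groups could not overlap under the rule for naming them, lay at or under 2.46e-05.

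**Figure D2:**
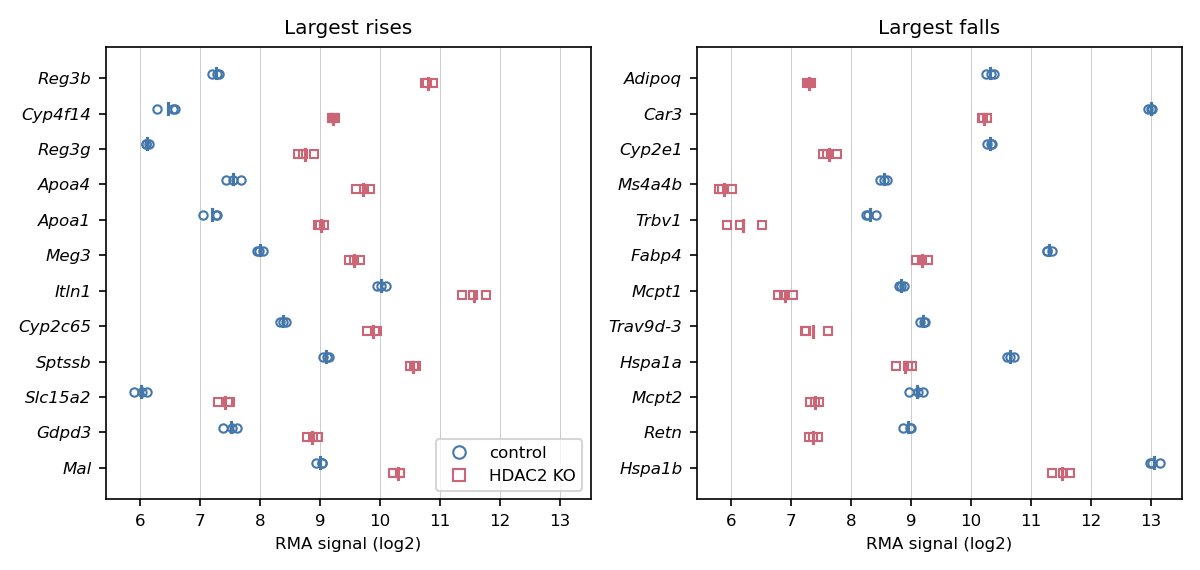
RMA signal in log2 units (horizontal axis) of the 12 genes with the largest rises and the 12 with the largest falls, with control arrays as circles, HDAC2 KO arrays as squares and a short line at each group mean. Reg3b had the largest rise, from a mean of 7.26 to 10.81, and Adipoq the largest fall, from 10.32 to 7.29.

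Of 47 gene lists tested, 22 passed camera, 10 higher and 12 lower in HDAC2 KO. With an estimated inter-gene correlation 0 of the 22 passed, with the adjusted p given below for each. The estimate lay below the preset 0.01 for the B cell and plasma cell (-0.0026), T cell (-0.0037), heat shock (-0.0074), Notch (-0.016) and ribosomal protein (0.0019) lists. A correlation above the preset value is therefore not why these were lost. For the other passing lists it lay above 0.01, up to 0.38 for the small intestinal enterocyte list. With an estimated correlation, camera also uses the residual degrees of freedom, 4 here. In simulated data with independent noise, the proliferation list was shifted by 0.15. Its camera adjusted p was 7.9e-31 with the preset correlation and 0.0088 with an estimated one. The estimated setting thus raised the adjusted p without correlated genes, so its values do not show that correlation caused the loss of any list. In fry, which asks only whether a list's members move one way on balance, 21 of the 22 had an adjusted p under 0.05, and 18 of the 22 passed camera on ranks. Of the 25 lists that did not pass camera, 9 had a fry adjusted p under 0.05, between 0.000879 and 0.0249. Higher on balance were the antimicrobial defence, glycolysis and hypoxia, histone and strain-variable lists, and lower were the deep crypt secretory and Paneth cell, MHC class II, cytokine and chemokine, fatty acid oxidation and fatty acid synthesis lists.

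Markers of differentiated absorptive cells were higher. In the absorptive colonocyte list, 10 of 22 members rose, 1 fell and 11 were not called (12 and 1 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 4.17e-05; adjusted p = 0.254 with an estimated correlation). Emp1 was 2.33-fold higher (1.22, SE 0.12), Tmigd1 1.68-fold, the surface keratin gene Krt20 1.40-fold and the carbonic anhydrase gene Car1 1.38-fold. Genes of small intestinal enterocytes were also higher: 6 of 9 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.000189; adjusted p = 0.281 with an estimated correlation). Besides Apoa4 and Apoa1, these were led by the intestinal alkaline phosphatase gene Alpi (2.37-fold) and the intestinal fatty acid binding protein gene Fabp2 (1.80-fold). Genes of mucin glycosylation rose in 7 of 22 cases and fell in 1 (7 and 1 adjusted over the list alone), among them the glycosyltransferase genes B3gnt6 (1.85-fold), St3gal4 (1.78-fold) and B4galnt2 (1.67-fold). That list's camera adjusted p was 0.0198 (adjusted p = 0.614 with an estimated correlation; 0.0907 on ranks; 0.0717 with the filter at the 60th percentile).

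Xenobiotic metabolism followed the same direction, with 8 of 23 members higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.0109; adjusted p = 0.402 with an estimated correlation; 0.0512 on ranks). Next to Cyp2c65, Cyp3a13 rose 1.89-fold and the retinaldehyde dehydrogenase gene Aldh1a1 1.31-fold. Cholesterol synthesis genes were higher in 7 of 17 cases and lower in 0 (10 and 0 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 8.49e-05; adjusted p = 0.297 with an estimated correlation), and Nsdhl rose 1.29-fold. In the NRF2 list, 4 of 15 members rose (4 adjusted over the list alone; camera adjusted p = 0.0485; adjusted p = 0.374 with an estimated correlation), led by Akr1b8 at 1.36-fold. The NRF2 call was lost with the replicate number as a block (adjusted p = 0.0696) and in 13 further alternatives (up to 0.128), and was kept in 3.

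Most proliferation genes were called higher, by small amounts. Of 25 members, 16 rose, 0 fell and 9 were not called (20 and 0 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 2.51e-07; adjusted p = 0.254 with an estimated correlation). Ccna2, which encodes cyclin A2, was 1.18-fold higher (0.24, SE 0.037, adjusted p = 0.00375), and the replicative helicase subunit genes Mcm5 and Mcm6 were 1.14-fold and 1.17-fold higher. The stem cell and Wnt target list went the other way, with 3 of 14 members lower (6 adjusted over the list alone) and a median of -0.11 (camera adjusted p = 0.0119; adjusted p = 0.254 with an estimated correlation). Ascl2, a transcription factor of intestinal stem cells, was 1.24-fold lower. For the stem cell marker Lgr5, at -0.14 (SE 0.033, adjusted p = 0.0248), the adjusted p lay between 0.0561 and 0.0957 without any array other than HDAC2 KO replicate 2, and the call was also lost without the signal filter (0.0819), with an intensity trend and robust variances (0.117) and over all probe sets (0.183). In the Notch list 3 of 12 members fell (5 adjusted over the list alone; camera adjusted p = 0.0325; adjusted p = 0.254 with an estimated correlation), including Notch1 (1.18-fold) and Notch2 (1.19-fold), and this call was lost without control replicate 3 (adjusted p = 0.0841), with array weights (0.108) and with the filter at the 60th percentile (0.0733).

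Secretory cell markers moved in both directions. Reg4, a marker of deep crypt secretory cells, was 2.26-fold lower, from 13.26 ± 0.020 to 12.09 ± 0.044 (SD, n = 3, limma adjusted p = 4.82e-07), and Lyz1, which encodes Paneth cell lysozyme, 1.23-fold lower, while Itln1 and Nupr1 (1.22-fold) were higher. The macrophage lysozyme gene Lyz2 was lower by a like amount, 1.24-fold, and the Lyz1 probe set is of a type that can bind several transcripts. In that list of 9 genes, 2 rose and 4 fell (3 and 4 adjusted over the list alone), its median of -0.027 and mean of 0.012 differed in sign, and camera gave an adjusted p of 0.447. Among 19 goblet cell genes, 2 were higher and 2 lower (4 and 2 adjusted over the list alone), and the median of -0.0084 had the opposite sign to the mean and to camera's direction (camera adjusted p = 0.892). Galnt12 was 1.23-fold higher and Atoh1, the secretory lineage regulator, 1.15-fold lower. Enteroendocrine genes rose in 4 and fell in 3 of 15 cases (4 and 3 adjusted over the list alone; camera adjusted p = 0.884; median -0.055, mean 0.0012), with Sst, encoding somatostatin, 1.19-fold higher and Chga, encoding chromogranin A, 1.17-fold lower. The tuft cell list passed (camera adjusted p = 0.0485; adjusted p = 0.374 with an estimated correlation) with 1 of 8 members called lower (2 adjusted over the list alone), and was lost in 3 alternatives and also without any array other than HDAC2 KO replicate 2, the adjusted p then lying between 0.0639 and 0.122. The called member, Alox5ap, is also expressed in leukocytes, whose markers fell as well, and its own call was lost in 8 of 16 alternatives.

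The antimicrobial defence list did not pass (camera adjusted p = 0.667): 3 of 15 members, Reg3b, Reg3g and Itln1, rose and 2 fell (4 and 2 adjusted over the list alone), its median of -0.020 having the opposite sign to its mean. Interferon response genes were higher in 7 and lower in 2 of 22 cases (9 and 2 adjusted over the list alone; camera adjusted p = 0.0413; adjusted p = 0.544 with an estimated correlation). Ifit1 rose 1.59-fold, Zbp1 1.42-fold and Rsad2 1.36-fold, while Ifi27l2a was 2.29-fold lower. That call was lost without control replicate 2 (adjusted p = 0.0509), control replicate 3 (0.0697) or HDAC2 KO replicate 1 (0.0526), and in 7 further alternatives (up to 0.408). Of 12 tested cytokine and chemokine genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.433), with the T cell chemokine gene Ccl5 1.67-fold lower and the epithelial chemokine gene Ccl28 1.22-fold lower.

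Markers of immune cells were lower. All 11 tested B cell and plasma cell genes fell (11 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 1.03e-11; adjusted p = 0.0718 with an estimated correlation). The immunoglobulin heavy chain gene Ighm was 2.62-fold lower, Cd79b 1.62-fold and Ms4a1, which encodes CD20, 1.60-fold. T cell, NK cell and intraepithelial lymphocyte genes fell in 4 of 7 cases (4 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 0.000331; adjusted p = 0.175 with an estimated correlation), and Cd3d was 2.59-fold lower (-1.37, SE 0.066). Macrophage and dendritic cell genes fell in 6 of 12 cases and rose in 1 (9 and 1 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.000122; adjusted p = 0.254 with an estimated correlation). Ptprc, the pan-leukocyte marker CD45, was 1.74-fold lower and the monocyte receptor gene Cd14 1.25-fold higher. Both mast cell genes tested, Mcpt1 and Mcpt2, fell, which left too few for camera, and 0 erythroid genes were tested.

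Markers of other tissues in a colon preparation moved apart. All 6 adipocyte genes fell (6 adjusted over the list alone), with a median of -1.02 (camera adjusted p = 7.59e-09; adjusted p = 0.146 with an estimated correlation), Plin4 being 1.37-fold lower beside Adipoq, Fabp4 and Retn. Endothelial genes fell in 5 of 13 cases (6 adjusted over the list alone; camera adjusted p = 0.00126; adjusted p = 0.254 with an estimated correlation), with Vwf 1.52-fold and Pecam1 1.27-fold lower. Smooth muscle genes rose in 6 of 15 cases and fell in 0 (11 and 0 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.000392; adjusted p = 0.254 with an estimated correlation), Cnn1 being 1.25-fold and Actg2 1.13-fold higher. Their signal was high in both groups, with Cnn1 at 12.38 ± 0.021 in control and 12.71 ± 0.025 in HDAC2 KO (SD, n = 3). Fibroblast and matrix genes (1 of 18 higher, 3 lower, as adjusted over the list alone; camera adjusted p = 0.577) and enteric neuron and glia genes (0 of 10 called; camera adjusted p = 0.447) did not pass. The exocrine pancreas list passed on 2 of 4 members (2 adjusted over the list alone; camera adjusted p = 0.0369; adjusted p = 0.254 with an estimated correlation), the lipase cofactor gene Clps at 1.57-fold and the elastase gene Cela1 at 1.18-fold lower, and was lost in 7 alternatives. The adjusted p was 0.116 without control replicate 3, 0.0645 without HDAC2 KO replicate 1, 0.114 on ranks, 0.0706 with the mean of probe sets, 0.0509 after a further quantile normalization, 0.0650 with array weights and 0.244 without the signal filter, where the list median turned to 0.029.

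Stress genes differed by class. Heat shock genes fell in 6 of 11 cases and rose in 1 (8 and 1 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.000400; adjusted p = 0.175 with an estimated correlation). Beside Hspa1a and Hspa1b, the chaperone gene Hsph1 was 1.62-fold lower, while the small heat shock protein gene Hspb1 was 1.44-fold higher. Genes of the unfolded protein response fell in 7 of 20 cases (10 adjusted over the list alone; median -0.13; camera adjusted p = 0.000208; adjusted p = 0.254 with an estimated correlation), including Manf (1.18-fold) and Hspa5 (1.13-fold), the latter encoding the chaperone BiP. The B cell and plasma cell list, whose plasma cells are rich in such chaperones, fell in the same samples. Immediate early genes rose in 8 of 16 cases and fell in 2 (11 and 2 adjusted over the list alone; median 0.16; camera adjusted p = 0.000848; adjusted p = 0.254 with an estimated correlation), with Egr1 and Atf3 each 1.26-fold higher and Klf2 1.39-fold lower. Ribosomal protein genes had 0 of 21 members called (0 adjusted over the list alone) and a median of -0.038 (camera adjusted p = 0.0485; adjusted p = 0.254 with an estimated correlation). That call was lost without any array other than control replicate 2, the adjusted p then lying between 0.0585 and 0.104, and also with the filter at the 60th percentile (0.0733), after centring each array (0.0972), after a further quantile normalization (0.110) and with the mean of probe sets (0.1845).

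**Figure D3:**
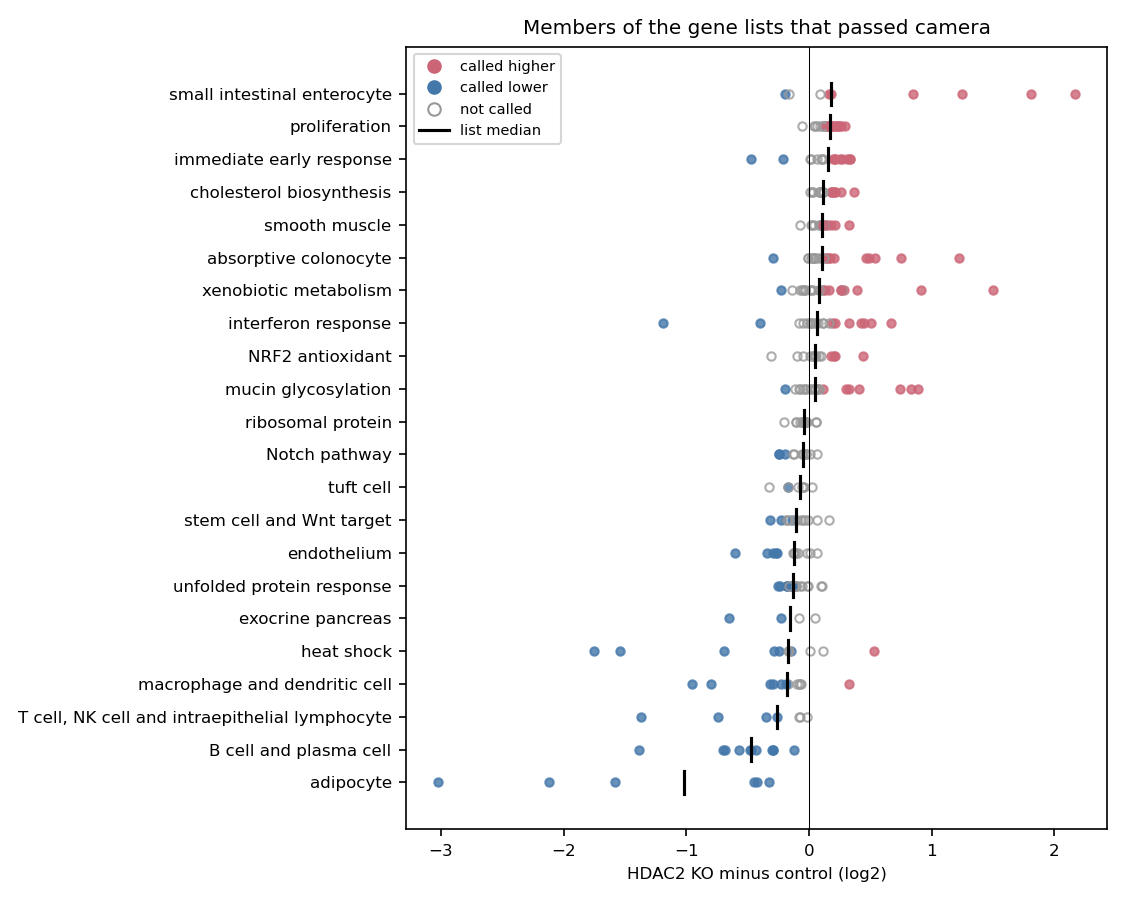
Difference between HDAC2 KO and control in log2 units (horizontal axis) of each tested member of the 22 gene lists that passed camera, with a black line at the list median, filled points for called genes and open grey points for the others. The adipocyte median lay lowest at -1.02, and the proliferation and small intestinal enterocyte medians both lay at 0.17.

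Fatty acid genes did not pass camera, in samples whose adipocyte markers differed as above. Of 19 fatty acid oxidation and ketogenesis genes, 2 rose and 3 fell (3 and 3 adjusted over the list alone), with the median of 0.0028 and mean of -0.059 differing in sign (camera adjusted p = 0.884; fry, lower, adjusted p = 0.00471). The fatty acid translocase gene Cd36 was 2.65-fold lower and Pdk4 1.49-fold higher. Of 13 fatty acid synthesis genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.350; fry, lower, adjusted p = 0.00288), with Scd1, the stearoyl-CoA desaturase, 2.20-fold lower and Elovl6 1.20-fold higher. Ion and solute transport genes rose in 7 and fell in 5 of 25 cases (9 and 5 adjusted over the list alone; camera adjusted p = 0.215), with the sodium-proton exchanger gene Slc9a3 1.45-fold higher and the proton-potassium ATPase gene Atp12a 1.22-fold lower. Junction genes had 1 of 22 members higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.755), namely Cldn4, higher by 0.59 on the log2 scale, and Cldn8, at 1.31-fold lower. Clock genes were called in both directions, 6 higher and 5 lower of 17 (7 and 5 adjusted over the list alone; camera adjusted p = 0.433), with Dbp 1.60-fold higher and Per2 1.48-fold lower. Their called share was well above the 17.9% over all genes tested. Camera asks for a shift in one direction, so it cannot judge a list whose members move both ways. The cause was not tested.

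The remaining metabolic and regulatory lists did not pass. Glycolysis and hypoxia genes rose in 5 and fell in 2 of 18 cases (7 and 2 adjusted over the list alone; camera adjusted p = 0.107), with Car9 1.27-fold higher and Bnip3 1.24-fold lower. Oxidative phosphorylation had 1 of 27 members called (0 adjusted over the list alone; camera adjusted p = 0.173). Of 13 p53 targets, 2 rose (3 adjusted over the list alone; camera adjusted p = 0.528), the median of -0.0044 and mean of 0.041 differing in sign, and the cell cycle inhibitor gene Cdkn1a was 1.25-fold higher. Of 6 histone genes, H2bc21 alone was called, at 1.42-fold higher (1 adjusted over the list alone; camera adjusted p = 0.205). Of 7 colon position genes, 2 rose and 1, Hoxb13, fell 1.20-fold (2 and 2 adjusted over the list alone; camera adjusted p = 0.884). Among 41 tested neighbours of Hdac2 in the annotation, 5 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.755; median -0.012, mean 0.022), led by Ncoa7 at 1.66-fold higher.

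Antigen presentation genes depended on the probe set. In the MHC class I list, 2 of 10 genes rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.884, median and mean differing in sign), and in the class II list 2 of 9 rose and 1 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.433). For H2-D1, of 9 probe sets 3 were called higher and 5 lower, with differences from -2.92, at a probe set whose HDAC2 KO signal of 4.01 lay far below the filter level, to 1.62. The probe set standing for the gene was 1.81-fold lower. For H2-K1, 2 of 4 probe sets were higher and 1 lower, and for H2-DMb2 2 of 3 were higher and 1 lower. Outside the rule for names, the class II genes H2-Aa and H2-Ab1 were not called by the probe sets standing for them (-0.087 and -0.033). Another probe set of each was lower, by -0.64 and -0.40 (limma adjusted p over all probe sets = 0.00124 and 0.0147), and their remaining probe sets were not called. The invariant chain gene Cd74, with a single probe set, was 1.27-fold lower, in samples in which markers of B cells, macrophages and dendritic cells, which express class II genes, fell as well.

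Checks on sex and strain differed between the groups. Xist, expressed from the inactive X chromosome of females, was high on every array, at 12.02 ± 0.023 in control and 11.54 ± 0.022 in HDAC2 KO (SD, n = 3, limma adjusted p = 4.46e-05). The probe sets standing for the Y-linked genes Eif2s3y and Kdm5d also lay above the filter level on every array, Kdm5d narrowly in control (6.96 ± 0.062, SD, n = 3). They were higher in HDAC2 KO by 0.61 (SE 0.095, adjusted p = 0.00360) and 0.67 (SE 0.11, adjusted p = 0.00419). The remaining probe sets of these genes lay far below that level, with group means between 3.14 and 3.89, and were not called. All probe sets of the Y-linked gene Uty lay below the filter level on every array (at most 6.34), and without detection calls these values do not show that Y-linked RNA was present in control. At this low signal 1 Uty probe set was higher in HDAC2 KO by 0.51 (limma adjusted p over all probe sets = 0.0126), and the others were not called. The sex-linked list, with 5 of 6 genes on the array and 3 tested, did not pass (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.670). The Y-linked gene Ddx3y, also in the list, was not among those tested, and its values are not described here. Of 9 tested genes known to vary between mouse strains, 3 were higher and 2 lower (5 and 2 adjusted over the list alone; camera adjusted p = 0.258), among them Erdr1 at 1.46-fold higher and H2-Ea at 1.42-fold lower.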

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

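The alternative that left out probe sets able to bind several transcripts was chosen after the data were seen. Genes changed in HDAC2 KO numbered 3506 with array weights (1874 higher, 1632 lower) and between 1130 and 2107 with 1 array left out (624 to 1222 higher, 506 to 885 lower), and lay within 1.5 times 1952 in all other alternatives. More genes were called higher than lower, other than without control replicate 3 (643 higher, 743 lower), without HDAC2 KO replicate 1 (632 higher, 642 lower) and over all probe sets (773 higher, 939 lower). Of the 1952 genes, 1107 remained called without the signal filter, where more genes were tested, and 736 when all probe sets were tested one by one. Genes with an unadjusted p under 0.05 and a fold of at least 1.5 numbered 85 with the filter at the 60th percentile, where fewer genes were tested, 488 over all probe sets and 45 at a fold of at least 2, against 162. Gene lists passing camera numbered 0 with an estimated correlation and 13 with the filter at the 60th percentile, against 22. The Hdac2 difference was -0.21 over all probe sets and -0.22 without probe sets able to bind several transcripts, with the call lost in both. Reversed were Mideas (-0.014) and Rps9 (0.87) with the mean of all probe sets, and Laptm5 (0.031) without probe sets able to bind several transcripts. The cause was not tested where none is named.

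With the mean of all probe sets, 11 genes described above kept their call with a log2 difference smaller by over 1.5 times: Meg3 (0.89), Car3 (-1.71), Fabp4 (-1.11), Trav9d-3 (-1.07), Emp1 (0.59), Lyz1 (-0.19), Notch2 (-0.13), Ighm (-0.47), Scd1 (-0.67), Slc9a3 (0.36) and Per2 (-0.17). The same held for H2-D1 (-0.41) and H2-Ea (-0.31), while H2-K1 and H2-DMb2 lost their call. Of 159 named genes called, 104 kept their call and direction in every alternative run and 116 in every one other than the test of all probe sets. The genes lost in the latter test alone include, of those described above, Actg2, Atoh1, Cela1, Chga, Hspa5, Mcm5, Mcm6, Notch1, Notch2 and Sst (adjusted p between 0.0523 and 0.0903). Of the 22 lists, 14 passed in every alternative other than the estimated correlation. With the replicate number as a block, 1943 genes, 162 genes of at least 1.5-fold and 21 lists passed, and 1735 of the 1952 genes stayed called. The calls of Retnlb, Cxcl1, Cd3e, Col6a2, Fn1 and Sesn1 were lost (adjusted p between 0.0518 and 0.0978) and those of Ltc4s, Stmn2, Perp and Rpl37 gained, so the counts of called members given for their lists move with them. Besides these and the NRF2 list, it changed no other call among the 195 genes and 22 lists. The difference between 3 prime and 5 prime control probe sets moved by less than the larger of the group SDs after a further quantile normalization and with each array left out. Without detection calls, signal over background is unknown, and low-signal genes were limited by the filter alone.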

Other observations

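The genes in this and the next paragraph fall outside the fixed rule for names and were chosen after their values were seen. Besides Meg3, 2 further genes of the same imprinted cluster were higher in HDAC2 KO, the non-coding RNA Rian 2.15-fold (1.10, SE 0.081, limma adjusted p = 7.47e-05) and Dlk1, which encodes a Notch ligand homolog, 1.29-fold (0.36, SE 0.036, adjusted p = 0.000387). The metallothionein gene Mt1 was 2.43-fold higher (1.28, SE 0.031, adjusted p = 1.80e-07), whereas Mt2 differed by 0.05 (SE 0.043, adjusted p = 0.475). Socs3, a feedback inhibitor of cytokine signalling, was 1.63-fold higher.

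The cytokine gene Ltb was 1.89-fold, the homing receptor gene Ccr7 1.82-fold, Glycam1 1.81-fold and the mucosal addressin gene Madcam1 1.52-fold lower, and no list of lymphoid tissue genes was tested. Of 10 tested immunoglobulin and T cell receptor V segments, all 10 were called, 3 higher and 7 lower. Iglv1 was 2.57-fold lower and Igkv6-14 2.40-fold lower, while the 3 higher segments, all of the immunoglobulin kappa chain, lay between 1.40-fold and 1.66-fold. Lpl, encoding lipoprotein lipase, was 2.66-fold lower and the lipase gene Pnliprp2 2.31-fold lower.

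Tests in the following 3 paragraphs, all but the counts over splits of the samples, were chosen after the results were seen. The probe sets standing for Xist and the Y-linked gene Eif2s3y both lay above the filter level on 6 of 6 arrays, but Uty lay below it on all of them. RNA of both sexes on each array may thus explain the signals but is not shown. Binding of the Y-linked probe sets to X-linked homologs is argued against as the cause of the higher Y-linked signal, since 8 homolog probe sets of Eif2s3x, Kdm5c and Kdm6a had a median difference of -0.16 (quartiles -0.19 and -0.15). Whether the arrays of a group share 1 RNA pool cannot be told. The median SD of the 10 V segments was 1.85 times that of genes of like level, and 0 of 1000 draws of such genes had one as large. A shared pool would leave technical spread only, but the technical spread of the V segment probe sets themselves was not measured. Pools of several mice and mixing of samples stay open, and the sex of the animals as a biological difference was not tested. The probe set standing for Xist was lower, and those for Eif2s3y and Kdm5d higher, on every HDAC2 KO array than on any control array. A difference in sex between the groups would coincide with genotype, and the calls could not tell it apart from HDAC2 loss. Where each array holds its own pool of RNA, the p-values measure the spread between pools, not between mice. Where the arrays of a group share 1 pool, they measure technical spread only.

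Adipocyte and lymphoid markers were lower in HDAC2 KO. A lower share of epithelium in the control samples, with all other tissues raised alike, would raise smooth muscle there too. The smooth muscle list was instead higher in HDAC2 KO, with a median of 0.11 (quartiles 0.063 and 0.14) and 14 of 15 members above 0. That argues against an even rise of all other tissues in control. It cannot judge a lower share of epithelium through fat or lymphoid tissue alone, which need not raise smooth muscle. Fat and lymphoid tissue carried into the control samples would lower adipocyte and B cell markers together, and 17 of 17 tested members of both lists were called lower. Their median SD on the control arrays was 0.045 against a median difference of -0.47, so carry-over that varied widely between control arrays is not seen. Whether the arrays of a group share an RNA pool cannot be told. With a shared pool this SD would be technical and could not show how far carry-over varied between mice. Carry-over and a change in the animals through HDAC2 loss, which was not tested, cannot be told apart. The dissection of the samples is not given in the sources used here.

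Probe sets of a single gene were called in opposite directions for 3 of 9 H2 genes with several probe sets, against 1 of 9001 other genes, Slc30a7 (2-sided Fisher's exact p = 2.76e-09). The H2 genes were singled out because of this pattern and were not matched for the number of probe sets, so that p restates it and excludes nothing. A candidate explanation is that the groups carry different H2 alleles in their mixed background. Among strain-variable genes listed before the data were examined, H2 genes left out, 4 of 8 were called, against 17.8% of other genes (1-sided Fisher's exact p = 0.0384). With 1 array left out, 2 to 4 of the 8 were called and the Fisher's exact p lay between 0.0494 and 0.236, and Itln1 could also rise through a change in the epithelium, so the explanation stays open, and a biological effect of HDAC2 loss was not tested.

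In 3 against 3 samples there are 10 splits, too few for a share under 0.05. The real split gave 1952 called genes, 162 genes of at least 1.5-fold and 22 lists, and for each of these 1 of the 10 splits, the real one, gave a count as large. The highest of the other splits gave 0 genes called by limma (at most 517 at an unadjusted p under 0.05), 0 genes of at least 1.5-fold and 6 lists. Every other split mixes the groups, so the real difference widens the spread within each side and shrinks the difference between the sides. Low counts of genes were therefore set in advance, and they do not measure what chance gives against 1952 or 162. Of the 4 splits that part all same-numbered pairs, the other splits gave 0 called genes, 0 genes of at least 1.5-fold and at most 4 lists. Camera with the preset correlation passed up to 6 lists on splits that mix the groups, where part of the group difference can remain between the sides.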
